A study of Rattus norvegicus with 24 samples.

How the data were processed

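PolyA RNA was sequenced from cultured neonatal rat ventricular myocytes of Sprague-Dawley rats in 24 libraries, 8 groups of 3. The groups cross doxorubicin or control treatment with a negative control mimic, a miR-222-3p mimic, a miR-455-3p mimic or both mimics. Mimics were transfected at 5 nM each with Lipofectamine RNAiMax the day after plating, treatment began 48 h later and lasted 24 h. The combination received 5 nM of each mimic, and the sources used here do not say whether wells with a single mimic were topped up to the same total. The dose is 4 uM in the sample protocol, recorded here, and 4 mM in the series text. The labels do not give the animals or days behind the replicates, so the p-values measure only the spread between these samples and take them as independent.

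The deposited table holds 21767 gene symbols, and its values are the authors' expected counts. Per the submitters' processing notes, Salmon and DESeq2 were used with the rat build Rnor_6.0; versions and the step each tool served are not given in the sources used here. The file calls itself filtered without stating the filter. Of its values 7.35% (38406) were not whole and were rounded to whole counts. In every library 3087 gene symbols were at 0. Totals per library ran from 17311955 to 25750311 counts, and 11469 to 13524 genes per library had at least 10 counts. A group at 0 allows at most 3 counts over its 3 libraries, the floor used for lower bounds on a fold; floors cover counting error only.

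Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by group (14303 genes kept), TMM scaling, a means model of the 8 groups over all 24 libraries, and the quasi-likelihood F test. P-values were adjusted by Benjamini-Hochberg within each comparison, and genes with an adjusted p under 0.05 were called. The standard error of a log2 fold change is its size divided by the square root of F. The comparisons were doxorubicin against none with each mimic condition, each mimic condition against the control mimic without and with doxorubicin, the combination against each single mimic with doxorubicin, the combination minus both single effects, and the doxorubicin effect with a mimic minus that with the control mimic. Adding miR-455 to miR-222 without doxorubicin used the same test.

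There were 28 gene lists of 534 distinct genes, of which 513 are in the table and 495 were tested. They cover damage and stress responses, the contractile and metabolic programmes, proliferation, inflammation, cell type markers and reported targets of each microRNA, and all are named in the report. They were tested with camera in limma 3.58.1 on voom values with a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 28 lists per comparison, again with an estimated correlation, and with fry. Of 392 list tests, without those for doxorubicin with a mimic, camera called 90 with the preset value and 7 with the estimated correlation: the autophagy and cell cycle lists for doxorubicin with the control mimic, the reported miR-222 targets for miR-222 with doxorubicin, the cell cycle list for the combination beyond the sum without doxorubicin, the p53 and autophagy lists for miR-222 in the response to doxorubicin, and the p53 list for both mimics in that response. For doxorubicin with a mimic camera called 30 of 84, of which 8 held with the estimated correlation. These were cardiac transcription factors with each mimic condition, autophagy with miR-455 and with both, the cell cycle with miR-222 and with both, and interferon-stimulated genes with miR-455. Fry tests whether a set moves 1 way on balance, or in its mixed form either way, and compares it with no other genes. The direction of a mimic effect was tested with fry on genes called for doxorubicin at a fold of at least 2 in the arms that share no library with it. An adjustment over the 3 mimics was added after the values were seen.

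Named genes followed a rule. Per comparison it takes the 6 higher and 6 lower called genes with the largest log2 fold change, a gene symbol, at least 5 CPM in the higher group and no overlap between the libraries of both groups, a condition not set for differences between effects. It adds up to 4 members of each list with the smallest p, members of the reported target list of the mimic, and always Nppa, Nppb, Cdkn1a, Mdm2, Myh6, Myh7, Cdkn1b, Hipk1 and Hmbox1; Top2b and Bbc3 were also to be named and are not analysed here. Which of the genes under the rule are dwelt on was chosen after their values were seen. The values of a few genes under the rule are not reported here.

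Comparisons, lists, tests and the naming rule were set before the data were examined. The alternatives set then were DESeq2 size factors in edgeR, the DESeq2 1.42.0 test, no filter, a filter of 1 CPM in 3 libraries, a fit of only the groups compared, a block for the replicate number, leaving out each library, and no minimum fold for the direction test. The alternatives chosen after seeing the data were leaving out the 4 libraries with the fewest genes, 2 and 4 surrogate variables from svaseq in sva 3.50.0, and limma-voom with library quality weights. A list of 17 hypoxia-induced genes was also chosen then. In simulated data 50 genes per fold were changed by 1.5, 2, 4 or 8-fold. For doxorubicin with the control mimic 0, 9, 30 and 44 were called, 0 in the wrong direction, and 4 unchanged genes. A single simulation without any change called 0 genes in each of 14 comparisons. Regrouped real libraries called up to 6386, so simulations do not cover their structure. Seed sites and GC content were not tested.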

Results

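The series asks whether mimics of miR-222-3p and miR-455-3p, alone and together, protect heart muscle cells from doxorubicin, an anthracycline used against cancer that damages the heart. Cultured neonatal rat ventricular myocytes received a negative control mimic, either of these mimics or both, at 5 nM each. Doxorubicin or control treatment followed 48 h later for 24 h. The sample protocol gives the dose as 4 uM and the series text as 4 mM, so it is not settled. Each of the 8 groups held 3 libraries. The value after a gene name is its log2 fold change ± SE, from 3 libraries against 3 unless stated. Genes said to rise or fall passed edgeR's quasi-likelihood F test at a Benjamini-Hochberg adjusted p under 0.05 over 14303 genes.

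The libraries of a group differed in ways that the labels do not name. Mitochondrially encoded transcripts took 14.3% ± 5.66 (SD, n = 3) of the counts with the control mimic alone and 21.0% ± 15.3 with the control mimic and doxorubicin, and single libraries ranged from 5.54% to 38.2%. The 4 libraries with the fewest genes at 10 or more counts were replicate 1 of the control mimic with doxorubicin (11469 genes) and replicate 2 of both mimics with doxorubicin (12289), then replicate 1 of the control mimic alone (12430) and replicate 3 of both mimics without doxorubicin (12467). Some libraries of a group were far closer than others: the chi-square per degree of freedom between counts was 5.96 for miR-222 replicates 1 and 2, 7.18 for miR-455 replicates 1 and 3 and 8.05 for replicates 1 and 2 of both mimics, all without doxorubicin. The other pairs of those groups had 132 to 601, and the 3 pairs of miR-455 with doxorubicin 8.11 to 10.2. Whether close pairs came from 1 culture is not known here. Without doxorubicin, the mean log2 CPM of 17 hypoxia-induced genes, a list chosen after the data were seen, was 4.49 ± 1.22 (SD, n = 3) with the control mimic. It was 5.98 ± 1.57 with miR-222, 6.35 ± 1.34 with miR-455 and 6.06 ± 1.52 with both.

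**Figure D1:**
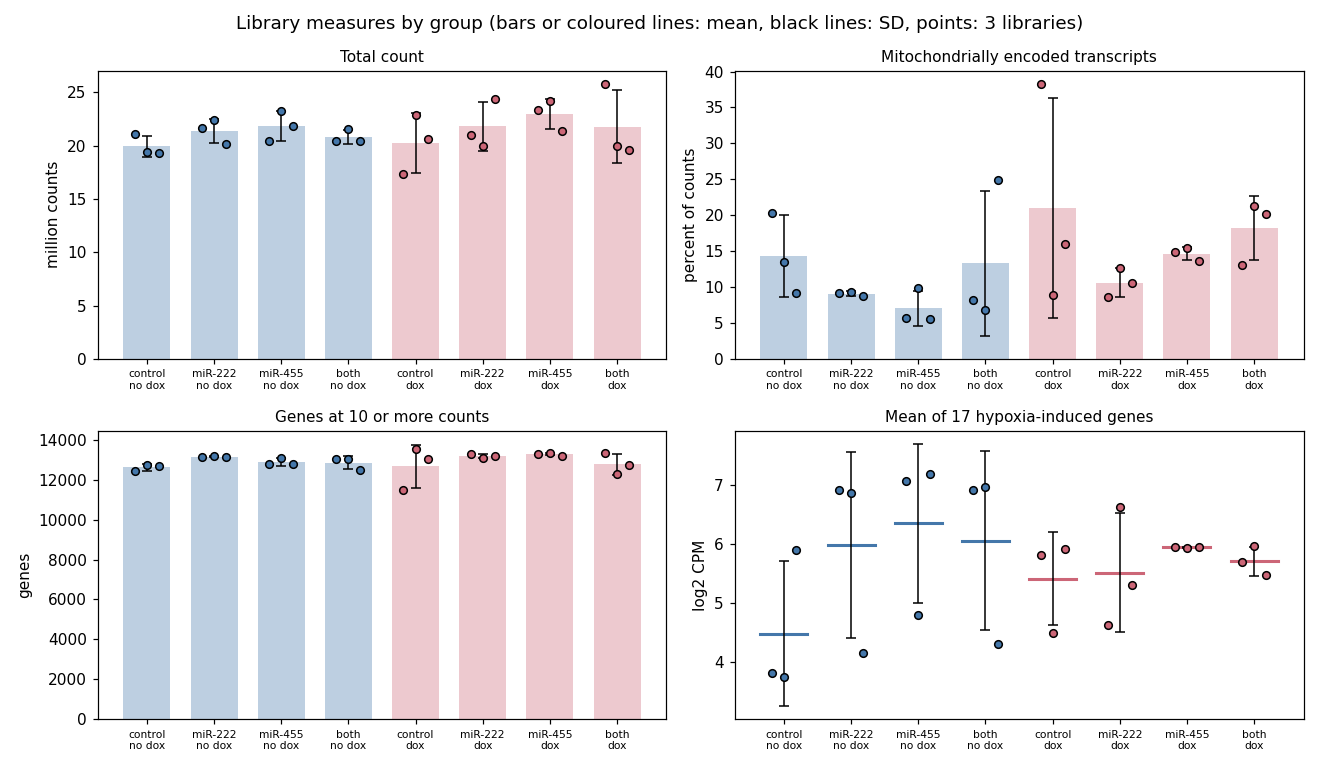
Total counts, share of mitochondrially encoded transcripts, genes at 10 or more counts and mean log2 CPM of the hypoxia-induced genes in each library, by group. Each point is 1 library.

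Doxorubicin with the control mimic raised the nuclear genes of the respiratory chain, the enzymes that pass electrons from fuel to oxygen. Of 26 measured members 24 rose (25 adjusted over the list alone), among them Sdha (2.21 ± 0.18), Ndufa9 (1.84 ± 0.18) and Uqcrc2 (2.08 ± 0.22). Fatty acid oxidation, the main fuel pathway of the heart, had 14 of 25 genes higher and 2 lower (15 and 3 adjusted over the list alone), with Acadl (2.11 ± 0.17), Acadm (2.33 ± 0.22), Decr1 (2.23 ± 0.21) and Hadh (2.42 ± 0.29) among those that rose. Of the autophagy and lysosome genes 12 of 19 rose and 1 fell (13 and 2 adjusted over the list alone), led by Lamp1 (2.08 ± 0.18), Ctsb (1.82 ± 0.20), Becn1 (1.55 ± 0.18) and Ctsl (1.65 ± 0.20). Glycolysis had 10 of 23 genes higher and 3 lower (11 and 3 adjusted over the list alone); Ldhb (1.88 ± 0.25) and Pgam1 (1.97 ± 0.50) rose, while Hk1 (-1.11 ± 0.21) and the glucose transporter Slc2a1 (-3.24 ± 0.80) fell. Targets of NRF2, the regulator of antioxidant genes, rose in 7 of 15 cases (7 adjusted over the list alone), among them Fth1 (2.29 ± 0.24), Nqo1 (3.93 ± 0.44), Txn1 (1.71 ± 0.22) and Prdx1 (1.87 ± 0.25). limma's camera with Benjamini-Hochberg adjustment over the 28 lists called these 5 lists higher than other genes. The respiratory chain had adjusted p = 7.52e-18, and 0.0513 with an estimated correlation (Benjamini-Hochberg). Fatty acid oxidation had adjusted p = 3.05e-07, and adjusted p = 0.218 with an estimated correlation (Benjamini-Hochberg), and autophagy and lysosome adjusted p = 3.77e-06, and adjusted p = 0.00361 with an estimated correlation. For glycolysis camera gave a Benjamini-Hochberg adjusted p = 0.0254, and adjusted p = 0.722 with an estimated correlation, and for NRF2 targets adjusted p = 5.07e-04, and adjusted p = 0.169 with an estimated correlation. The mitochondrially encoded transcripts, whose share was highest in replicate 1 of this doxorubicin group, had Mt-co1 (1.72 ± 0.48) and Mt-atp8 (1.55 ± 0.55) higher out of 13 genes. Camera in limma gave them a Benjamini-Hochberg adjusted p = 0.181, and 0.746 with an estimated correlation.

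Cell cycle genes fell and some p53 targets rose with doxorubicin, a poison of type II topoisomerases. Of 30 cell cycle genes 23 fell (25 adjusted over the list alone, with 1 higher), among them Bub1b (-3.26 ± 0.38), Cenpf (-3.95 ± 0.49), Tpx2 (-3.40 ± 0.42) and Plk1 (-2.89 ± 0.41) and the topoisomerase Top2a (-6.09 ± 0.88). Targets of p53, the regulator that stops damaged cells from dividing, rose in 10 of 27 cases (12 adjusted over the list alone, with 1 lower), with Rrm2b (2.36 ± 0.29), Ei24 (1.33 ± 0.17), Pmaip1 (2.19 ± 0.30), Tp53inp1 (1.93 ± 0.40), Cdkn1a (2.59 ± 0.61) and Mdm2 (1.87 ± 0.45) among them. DNA repair had 3 of 23 genes higher and 7 lower (3 and 7 adjusted over the list alone), with Brca1 (-1.98 ± 0.44) and Exo1 (-3.85 ± 0.93) lower and Lig4 (1.34 ± 0.33) higher. Interferon-stimulated genes rose in 14 of 21 cases (15 adjusted over the list alone), led by Irf7 (4.08 ± 0.36), Gbp2 (3.72 ± 0.46), Bst2 (5.67 ± 0.89) and Rsad2 (3.40 ± 0.58). NF-kB targets and cytokines had 7 of 18 genes higher and 1 lower (7 and 1 adjusted over the list alone), with Cxcl10 (3.26 ± 0.50), Csf1 (1.61 ± 0.25), Icam1 (2.15 ± 0.44) and Ccl2 (3.46 ± 0.78) higher. limma's camera with Benjamini-Hochberg adjustment gave adjusted p = 3.53e-13, and 0.0175 with an estimated correlation for the cell cycle. For p53 targets it gave adjusted p = 0.0017, and 0.0683 with an estimated correlation. DNA repair had adjusted p = 0.0254, and 0.484 with an estimated correlation (Benjamini-Hochberg). Camera gave a Benjamini-Hochberg adjusted p = 3.77e-06, and 0.0815 with an estimated correlation for interferon-stimulated genes. NF-kB targets and cytokines had adjusted p = 0.0249, and 0.132 with an estimated correlation (Benjamini-Hochberg).

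Cardiac transcription factors, which hold the heart muscle programme in place, fell in 9 of 15 cases with doxorubicin (12 adjusted over the list alone), with Tbx20 (-2.09 ± 0.29), Myocd (-3.42 ± 0.50), Prox1 (-2.30 ± 0.41) and Tbx5 (-2.23 ± 0.45) lowest in p. limma's camera gave a Benjamini-Hochberg adjusted p = 7.51e-05, and 0.0517 with an estimated correlation. Among 12 cardiac stress genes, which failing hearts tend to raise, Xirp1 (-7.01 ± 0.74), Rcan1 (-4.10 ± 0.58) and Ccn1 (-2.08 ± 0.46) and 2 others fell. The atrial natriuretic peptide gene Nppa (3.17 ± 0.51) rose (1 higher and 6 lower adjusted over the list alone). Its relative Nppb (0.04 ± 0.36) and the myosin heavy chains Myh6 (-0.09 ± 0.36) and Myh7 (0.22 ± 0.51) did not pass. Sarcomere genes rose in 9 of 22 cases and fell in 1 (9 and 2 adjusted over the list alone), with Myl2 (2.08 ± 0.22), Tnni1 (1.72 ± 0.30), Myl3 (2.07 ± 0.40) and Tnnt2 (1.34 ± 0.27) higher. Calcium handling and ion channel genes had 3 higher and 5 lower of 22 (4 and 5 adjusted over the list alone), with Casq2 (1.81 ± 0.26) higher and Slc8a1 (-2.81 ± 0.48) and Cacnb2 (-3.62 ± 0.65) lower. Fibroblast and matrix markers had 5 higher and 1 lower of 17 (8 and 1 adjusted over the list alone), with Timp1 (1.63 ± 0.23) and Mmp2 (2.11 ± 0.30) higher. These last 4 lists did not pass limma's camera, with Benjamini-Hochberg adjusted p = 0.0618, 0.0646, 0.527 and 0.0587.

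The remaining fixed lists did not pass limma's camera in this comparison (lowest Benjamini-Hochberg adjusted p = 0.18, for endoplasmic reticulum stress). Endoplasmic reticulum stress had 1 of 18 genes higher and 4 lower, with Xbp1 (-1.22 ± 0.18) and Vldlr (-1.75 ± 0.38) lower. Doxorubicin targets and transporters had 3 of 14 higher and 1 lower, with the drug exporter Abcb1a (2.86 ± 0.30) higher. Cell cycle inhibitors and G1 cyclins had 4 of 15 higher and 2 lower, with Cdkn1c (3.60 ± 0.47) and Ccnd1 (1.29 ± 0.23) higher and Rbl1 (-2.54 ± 0.48) and Cdkn1b (-1.03 ± 0.33) lower. Apoptosis regulators had 2 of 21 higher and 2 lower, ferroptosis and iron genes 3 of 15 higher and 2 lower, immediate early genes 1 of 20 higher and 5 lower, and heat shock genes 1 of 13 each way. Markers of smooth muscle and pericytes had 1 of 10 higher and 3 lower, endothelial markers 1 of 10 each way, and macrophage and leukocyte markers 3 of 11 higher. Reported miR-222 targets had 2 of 19 higher and 4 lower, and reported miR-455 targets 3 of 15 each way. Adjusted over the list alone, the counts differed in 4 of these lists: 4 higher and 3 lower for cell cycle inhibitors and G1 cyclins, 3 and 4 for smooth muscle and pericytes, 4 and 5 for miR-222 targets, and 4 and 3 for miR-455 targets.

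In all, 2171 genes rose and 1765 fell with doxorubicin and the control mimic. A4galt (-7.46 ± 0.96), Pdcd5 (-6.99 ± 1.92), Depp1 (-6.80 ± 0.64) and B3galt2 (-5.96 ± 1.29) fell furthest beside Xirp1 and Top2a. Genes listed at 0 in all 3 control libraries gave lower bounds against a floor of 3 counts over the group: Nkx6-1 rose at least 472-fold, Tmem200c at least 285-fold and Palm3 at least 142-fold. For Gsta2 (9.08 ± 10.6 CPM, SD, n = 3) the bound was 215-fold, and 74.0-fold without doxorubicin control replicate 1. For Hsd11b2 (5.72 ± 4.58 CPM) it was 136-fold, and 76.3-fold without doxorubicin control replicate 2. Gpr50 rose from 0.0149 ± 0.0258 to 10.1 ± 4.96 CPM (SD, n = 3). A fit of these 6 libraries alone called 1437 genes.

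**Figure D2:**
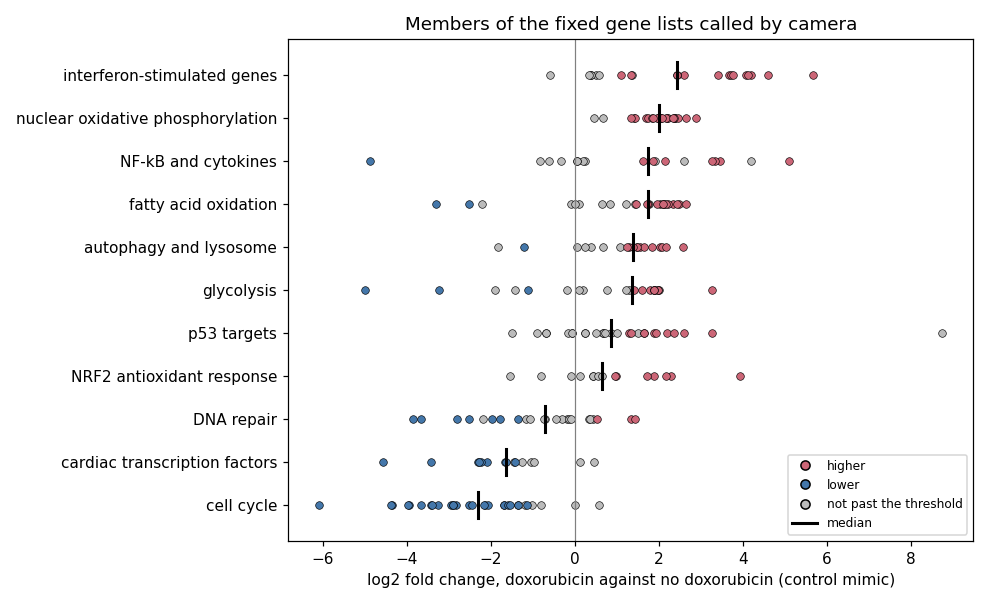
Log2 fold changes of the members of the 11 gene lists that camera called for doxorubicin against none, with the control mimic. Each point is 1 gene.

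Doxorubicin with a mimic raised 1110 genes and lowered 983 (miR-222), 1290 and 1303 (miR-455), and 1123 and 1035 (both). All 4 doxorubicin comparisons shared 589 higher and 448 lower genes. At most 1.19 were expected in each if the calls were independent. The respiratory chain list had 15 of 26 genes higher with miR-222 (20 adjusted over the list alone), 16 with miR-455 (23) and 13 with both (18), with Sdha at 1.47 ± 0.17, 1.42 ± 0.17 and 1.52 ± 0.17. Of 30 cell cycle genes 16 fell in each of these 3 comparisons (17, 19 and 18 adjusted over the list alone), with Bub1b at -2.85 ± 0.37, -2.44 ± 0.37 and -3.31 ± 0.38. Cardiac transcription factors fell in 9, 7 and 9 of 15 cases (10, 9 and 9 adjusted over the list alone), with Prox1 at -3.03 ± 0.41, -2.87 ± 0.41 and -2.95 ± 0.41. Interferon-stimulated genes rose in 3 of 21 cases with miR-222, 17 with miR-455 and 4 with both (3, 19 and 5 adjusted over the list alone), with Irf7 at 1.95 ± 0.33, 4.23 ± 0.36 and 2.41 ± 0.34. Fibroblast and matrix markers rose in 5, 4 and 5 of 17 cases (6, 4 and 6 adjusted over the list alone), with Mmp2 at 2.28 ± 0.30, 2.18 ± 0.30 and 2.45 ± 0.30. limma's camera with Benjamini-Hochberg adjustment gave these lists adjusted p from 1.27e-12 to 0.0123. With an estimated correlation, the adjusted p for the cell cycle was 0.0452, 0.0508 and 0.0318 (limma, Benjamini-Hochberg), that for cardiac transcription factors 0.0452, 0.021 and 0.0318, and those for the other 3 lists from 0.021 to 0.358. Leaving out 1 library moved the counts to 1187 and 1210 genes (miR-222 replicates 1 and 2) and 1281 and 1289 (miR-222 with doxorubicin replicates 1 and 3). For miR-455 the counts moved to 1542 and 1544 (miR-455 replicates 1 and 3) and 1626, 1566 and 1600 (miR-455 with doxorubicin replicates 1 to 3), and for both mimics to 1330, 1371 and 1377 (replicates 1 and 2 without and replicate 3 with doxorubicin).

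Without doxorubicin, the miR-222 mimic lowered several cardiac stress and matrix genes and raised several interferon-stimulated genes and p53 targets. Cardiac stress genes fell in 4 of 12 cases (9 adjusted over the list alone), Fhl1 (-1.60 ± 0.32), Xirp1 (-2.56 ± 0.60), Nppb (-1.57 ± 0.37) and Ccn1 (-1.49 ± 0.45). Fibroblast and matrix markers fell in 5 of 17 cases (9 adjusted over the list alone), with Fn1 (-1.22 ± 0.21), Timp1 (-1.25 ± 0.23), Thy1 (-2.57 ± 0.56) and Lum (-2.20 ± 0.53). Interferon-stimulated genes had 9 of 21 higher and 1 lower (10 and 1 adjusted over the list alone), with Rsad2 (4.30 ± 0.60), Oasl (3.04 ± 0.66), Ifit3 (2.38 ± 0.55) and Bst2 (3.52 ± 0.85) higher. Targets of p53 rose in 7 of 27 cases (10 adjusted over the list alone), with Tp53inp1 (2.15 ± 0.40), Xpc (1.05 ± 0.25), Cdkn1a (2.55 ± 0.61) and Ccng1 (1.22 ± 0.32). Fatty acid oxidation had 8 of 25 genes higher (11 adjusted over the list alone), with Acaa2 (1.88 ± 0.34), Acadl (0.76 ± 0.16), Acadvl (1.56 ± 0.36) and Pdk4 (2.80 ± 0.76). The respiratory chain had 1 of 26, Cox5a (0.88 ± 0.23) (8 adjusted over the list alone). Glycolysis had 3 of 23 genes higher, Pgam2 (2.16 ± 0.51), Gpi (1.75 ± 0.51) and Slc16a1 (0.82 ± 0.25) (14 adjusted over the list alone), beside a hypoxia-gene mean that was higher in 2 of the 3 miR-222 libraries than in any control library. Cell cycle genes fell in 4 of 30 cases (10 adjusted over the list alone), Ccne2 (-2.22 ± 0.56), Mcm4 (-1.49 ± 0.38), Mcm3 (-1.65 ± 0.49) and Mcm2 (-0.83 ± 0.25). Reported miR-222 targets went both ways: Ets1 (-1.68 ± 0.25), Hipk1 (-0.75 ± 0.15), Hmbox1 (-1.55 ± 0.46) and Timp3 (-2.55 ± 0.74) and 1 other fell, and Cdkn1c (2.51 ± 0.45) and Bmf (2.78 ± 0.82) and 1 other rose, of 19. limma's camera with Benjamini-Hochberg adjustment called 9 lists, with adjusted p from 1.46e-07 for the cell cycle to 0.0483 for DNA repair. With an estimated correlation, camera gave Benjamini-Hochberg adjusted p from 0.14 to 0.459 for these 9 lists: p53 targets, stress genes (1.04e-04 with the preset value), respiratory chain (1.48e-04), fatty acid oxidation (3.63e-05), glycolysis (1.56e-04), interferon-stimulated genes (9.91e-04), cell cycle, DNA repair and fibroblast markers (8.08e-05). The 23 repair genes gave no edgeR call (2 higher and 3 lower adjusted over the list alone, 2 higher and 5 lower at an unadjusted p under 0.05, and DESeq2 called 2 higher and 3 lower).

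The test called 644 genes higher and 639 lower with miR-222 and no doxorubicin. Slc4a1 was listed at 0 with the control mimic and rose at least 190-fold to 8.02 ± 1.78 CPM (SD, n = 3). Sctr and Kcna5 rose from 0.0149 ± 0.0258 CPM each to 10.7 ± 8.55 and 6.01 ± 3.59 CPM. Syt7 (6.82 ± 1.19), Kcnip2 (6.63 ± 1.62) and Angptl8 (5.78 ± 1.44) also rose, and Necab1 (-4.18 ± 0.73), Ptchd1 (-3.86 ± 0.98), Frem1 (-3.39 ± 0.47), Vsnl1 (-3.30 ± 0.65) and Thbd (-3.24 ± 0.62) fell. Myh7 (-2.09 ± 0.53), the slow myosin heavy chain, fell, and Nppa (0.11 ± 0.47), Mdm2 (1.08 ± 0.44), Myh6 (0.49 ± 0.36) and Cdkn1b (0.12 ± 0.33) did not pass. The count was 496 or 675 without control replicate 1 or 2 and 300 or 302 without miR-222 replicate 1 or 2, and 2832 without the 4 libraries with the fewest genes.

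The miR-455 mimic without doxorubicin raised several sarcomere genes. Sarcomere genes rose in 4 of 22 cases, Myl4 (3.17 ± 0.34), Myl2 (1.69 ± 0.22), Des (1.68 ± 0.37) and Myl3 (1.58 ± 0.40) (6 adjusted over the list alone). Nppa (2.71 ± 0.50) and skeletal actin Acta1 (4.09 ± 0.76) rose among the stress genes. Fatty acid oxidation had 3 of 25 genes higher, Acaa2 (2.01 ± 0.34), Acadvl (1.49 ± 0.36) and Cpt1b (2.15 ± 0.55) (7 adjusted over the list alone). Glycolysis had 1 of 23, Pfkp (1.08 ± 0.26) (15 adjusted over the list alone). Beside this stood a hypoxia-gene mean above that of every control library in 2 of the 3 miR-455 libraries. Cell cycle genes fell in 4 of 30 cases, Mcm4 (-1.79 ± 0.38), Tyms (-0.94 ± 0.23), Cenpf (-1.66 ± 0.44) and Kif20a (-0.90 ± 0.25) (17 adjusted over the list alone). DNA repair genes fell in 3 of 23, among them Rpa1 (-0.87 ± 0.19) and Brca1 (-1.67 ± 0.43) (4 adjusted over the list alone). limma's camera with Benjamini-Hochberg adjustment gave adjusted p = 0.00104 for sarcomere genes, 0.00104 for fatty acid oxidation, 3.79e-06 for glycolysis, 4.61e-11 for the cell cycle and 0.00589 for DNA repair. With an estimated correlation all lost the call, as did 3 further lists, with a Benjamini-Hochberg adjusted p = 0.0708 for the cell cycle and from 0.457 to 0.468 for the other 7 by limma's camera. The further lists were called with the preset value and held no gene passing edgeR: the respiratory chain higher (median 0.68, adjusted p = 5.07e-05), mitochondrially encoded genes lower (median -1.52, adjusted p = 2.74e-05) and reported miR-455 targets lower (median -0.46, adjusted p = 0.0317). At an unadjusted p under 0.05 edgeR gave 15 of 26 respiratory chain genes higher, 5 of 13 mitochondrially encoded genes lower and 5 of 15 reported targets lower, and DESeq2 called 9, 1 and 3. Adjusted over the list alone, 15 respiratory chain genes were higher and 3 reported targets lower by edgeR. The mitochondrially encoded share was 7.03% ± 2.43 (SD, n = 3) in these libraries, against 14.3% ± 5.66 in the controls.

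In this comparison 353 genes rose and 322 fell. Mfsd4a (4.92 ± 1.41), Hapln4 (4.78 ± 1.14), Fads6 (4.64 ± 0.91) and Gipr (4.53 ± 1.04) rose furthest, and Necab1 (-3.42 ± 0.71), Scn1a (-3.01 ± 0.62), Dgkb (-2.91 ± 0.78), Ptn (-2.79 ± 0.65), Mnda (-2.77 ± 0.67) and Nrep (-2.63 ± 0.62) fell furthest by the rule used. Nppb (0.80 ± 0.37), Cdkn1a (1.90 ± 0.59), Mdm2 (1.26 ± 0.44), Myh6 (0.62 ± 0.36), Myh7 (1.69 ± 0.52) and Cdkn1b (0.97 ± 0.33) did not pass. Leaving out 1 library gave 108, 201 and 1163 genes for control replicates 1 to 3 and 16, 1987 and 41 for miR-455 replicates 1 to 3. A fit of these 6 libraries alone gave 2.

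Both mimics without doxorubicin lowered several cardiac stress and matrix genes. Cardiac stress genes fell in 4 of 12 cases, Xirp1 (-2.82 ± 0.60), Nppb (-1.75 ± 0.37), Fhl1 (-1.34 ± 0.32) and Ccn1 (-1.49 ± 0.45) (1 higher and 7 lower adjusted over the list alone). Fibroblast and matrix markers fell in 5 of 17 cases (6 adjusted over the list alone), with Timp1 (-1.05 ± 0.22), Fn1 (-0.96 ± 0.21), Thy1 (-2.42 ± 0.55) and Pdgfra (-1.36 ± 0.31). Smooth muscle and pericyte markers fell in 2 of 10, Pdgfrb (-1.65 ± 0.40) and Smtn (-1.08 ± 0.30) (2 adjusted over the list alone). Interferon-stimulated genes had 6 of 21 higher and 1 lower (11 and 1 adjusted over the list alone), with Rsad2 (3.68 ± 0.58), Bst2 (3.67 ± 0.85) and Oasl (2.72 ± 0.65) higher and Ifitm3 (-1.09 ± 0.21) lower. Targets of p53 had 6 of 27 higher and 1 lower (10 and 1 adjusted over the list alone), with Rrm2b (1.41 ± 0.28), Tp53inp1 (2.01 ± 0.40), Fas (1.36 ± 0.32) and Cdkn1a (2.36 ± 0.60) higher. Fatty acid oxidation had 8 of 25 genes higher (12 adjusted over the list alone), with Acaa2 (1.93 ± 0.34), Cpt2 (1.03 ± 0.22), Acadvl (1.64 ± 0.36) and Hadhb (1.17 ± 0.27). The respiratory chain had 3 of 26, Cox5a (0.92 ± 0.23), Ndufv2 (1.16 ± 0.30) and Ndufa9 (0.66 ± 0.18) (10 adjusted over the list alone). Glycolysis had 1 of 23, Pgam2 (2.38 ± 0.51) (12 adjusted over the list alone). The hypoxia-gene mean stood above that of every control library in 2 of the 3 combination libraries. NRF2 targets rose in 5 of 15 cases (9 and 1 lower adjusted over the list alone), with Me1 (0.77 ± 0.19), Fth1 (0.94 ± 0.23), Ftl1 (2.58 ± 0.66) and Gsr (0.78 ± 0.22). Endoplasmic reticulum stress genes rose in 2 of 18, Ddit3 (3.09 ± 0.67) and Vldlr (1.44 ± 0.37) (2 adjusted over the list alone). Cell cycle genes fell in 2 of 30 cases, Mcm2 (-1.05 ± 0.25) and Mcm4 (-1.38 ± 0.38) (3 adjusted over the list alone). The reported miR-222 targets Ets1 (-1.77 ± 0.25) and Hipk1 (-0.69 ± 0.15) fell while Hmbox1 (-1.19 ± 0.46) did not pass. limma's camera called these 11 lists with Benjamini-Hochberg adjusted p from 4.88e-06 (respiratory chain) to 0.0274 (endoplasmic reticulum stress); with an estimated correlation each lost the call, with adjusted p from 0.205 to 0.403.

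The combination raised 525 genes and lowered 485 without doxorubicin. Kcnip2 (6.60 ± 1.62), Syt7 (6.49 ± 1.18), Efhd1 (5.95 ± 1.61), Klhdc8a (5.31 ± 1.29), Slc38a3 (5.24 ± 1.08) and Tubb4a (5.15 ± 0.74) rose furthest and Necab1 (-4.10 ± 0.73), Egr2 (-3.85 ± 0.51), Thbd (-3.69 ± 0.64), Frem1 (-3.65 ± 0.47) and Rasgrp3 (-3.48 ± 0.73) fell furthest. Myh7 (-2.08 ± 0.53) fell as well, and Nppa (0.36 ± 0.47), Mdm2 (1.38 ± 0.44), Myh6 (0.41 ± 0.36) and Cdkn1b (-0.08 ± 0.33) did not pass. The count was 583 or 509 without control replicate 1 or 2. It was 267, 284 or 2718 without combination replicate 1, 2 or 3, of which replicate 3 had the highest mitochondrially encoded share of the group (24.9%). A fit of these 6 libraries alone called 0 genes by edgeR, where the fit of all 24 gave 3259 at an unadjusted p under 0.05 and DESeq2 1887 after adjustment.

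With doxorubicin, the miR-222 mimic lowered its reported targets as a set and several sarcomere genes. Of 19 reported targets 3 fell (3 adjusted over the list alone): the kinase Hipk1 (-0.69 ± 0.15), the homeobox gene Hmbox1 (-1.72 ± 0.47) and the receptor Kit (-1.31 ± 0.36). Hmbox1 was at 14.5 CPM in doxorubicin control replicate 1, 3.61 and 3.79 in replicates 2 and 3, and 2.01 to 2.31 with miR-222. The size of its fall thus rests largely on control replicate 1. limma's camera gave the list a Benjamini-Hochberg adjusted p = 9.58e-04, and 0.043 with an estimated correlation. With 6 libraries with the mimic against 6 without, chosen after the data were seen, camera gave adjusted p = 0.0266, and 0.263 with an estimated correlation, which lost the call. Sarcomere genes fell in 5 of 22 cases (5 adjusted over the list alone), Ldb3 (-1.85 ± 0.27), Myom2 (-3.02 ± 0.76), Myh7 (-2.04 ± 0.53) and Nebl (-3.08 ± 0.80) and 1 other. Calcium handling genes fell in 2 of 22, the gap junction gene Gja1 (-1.78 ± 0.41) and phospholamban, Pln (-2.31 ± 0.64) (1 higher and 4 lower adjusted over the list alone). Fibroblast and matrix markers fell in 3 of 17 cases, Timp1 (-1.60 ± 0.23), Thy1 (-2.40 ± 0.55) and Lum (-2.07 ± 0.53) (4 adjusted over the list alone). limma's camera gave Benjamini-Hochberg adjusted p = 7.28e-04, 0.0407 and 0.026 for these 3 lists and 7.28e-04 for mitochondrially encoded genes, which were lower (median -1.68) although edgeR called 0 of 13 (8 lower at an unadjusted p under 0.05, and DESeq2 called 2 lower). With an estimated correlation these 4 lists had Benjamini-Hochberg adjusted p from 0.528 to 0.626. The mitochondrially encoded share was 10.6% ± 2.04 (SD, n = 3) with miR-222 and 21.0% ± 15.3 with the control mimic. Irf7 (-1.52 ± 0.32), Ctsb (-0.90 ± 0.20), Sdhd (-1.46 ± 0.25), Ccnd1 (-1.18 ± 0.23) and Rpa1 (-1.39 ± 0.19) fell as well.

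The test called 227 genes higher and 338 lower with miR-222 in doxorubicin. Pvalb (4.96 ± 1.19), Kcnv2 (4.19 ± 0.60), Gdf10 (4.17 ± 0.85), G0s2 (3.45 ± 0.89), Lrrc4b (3.44 ± 0.68) and Alox15 (3.16 ± 0.73) rose furthest and Tox (-3.80 ± 0.59), Flot2 (-3.56 ± 0.38), Unc13b (-3.34 ± 0.34), Gca (-3.31 ± 0.42), Tmeff1 (-3.23 ± 0.51) and Kdr (-3.17 ± 0.69) fell furthest. Nppa (-1.10 ± 0.48), Nppb (-1.06 ± 0.37), Cdkn1a (0.36 ± 0.57), Mdm2 (-0.77 ± 0.44), Myh6 (0.08 ± 0.36) and Cdkn1b (-0.36 ± 0.33) did not pass. The count was 343 without control replicate 1 and 363, 279 and 263 without miR-222 replicates 1 to 3, all with doxorubicin.

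With doxorubicin, the miR-455 mimic lowered the reported target Ei24 (-0.89 ± 0.17), which p53 induces, 1 of 15 reported targets called (2 adjusted over the list alone). limma's camera gave the list a Benjamini-Hochberg adjusted p = 0.0222, and 0.601 with an estimated correlation. Of 22 calcium handling and channel genes 1 fell, the potassium channel Kcnh2 (-2.14 ± 0.45) (2 adjusted over the list alone), with a Benjamini-Hochberg adjusted p = 0.008, and adjusted p = 0.733 with an estimated correlation by limma's camera. Sdha (-0.80 ± 0.17), Acadl (-0.62 ± 0.16) and Txn1 (-0.88 ± 0.21) fell. The p53 target Perp (-2.06 ± 0.26), the lactate carrier Slc16a1 (-1.55 ± 0.26), the chaperone Calr (-1.06 ± 0.24) and the sarcomere protein gene Myom1 (-2.18 ± 0.45) fell as well. Nppb (1.43 ± 0.37), the apoptosis regulator Diablo (0.97 ± 0.19), Ndufv2 (1.29 ± 0.30) and Acaa2 (1.55 ± 0.33) rose.

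The test called 94 genes higher and 264 lower with miR-455 in doxorubicin. Med30 (3.20 ± 0.44), Galc (2.65 ± 0.41), Rab3b (2.46 ± 0.48), Chchd6 (2.17 ± 0.47), Ddt (2.17 ± 0.42) and Scml2 (2.07 ± 0.52) rose furthest and Cox6a1 (-3.22 ± 0.48), Scoc (-3.08 ± 0.38), Ampd3 (-3.08 ± 0.49), Gca (-2.99 ± 0.41), Sh3bgrl (-2.73 ± 0.59) and Mlf1 (-2.73 ± 0.58) fell furthest. Nppa (0.62 ± 0.47), Cdkn1a (-0.04 ± 0.57), Mdm2 (-0.38 ± 0.44), Myh6 (-0.17 ± 0.36), Myh7 (-0.64 ± 0.51) and Cdkn1b (0.74 ± 0.33) did not pass. The 3 miR-455 libraries with doxorubicin were the most alike of any group, with a median SD of 0.146 in log2 CPM over 14303 genes against 0.593 in the doxorubicin controls. If they came from 1 culture, which the labels do not say, n = 3 overstates the number of independent samples. Leaving out replicates 1, 2 and 3 gave 152, 146 and 145 genes.

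Both mimics with doxorubicin raised 2 genes of the endoplasmic reticulum stress list and lowered 2 G1 cyclins and 2 matrix markers. The lipoprotein receptor Vldlr (2.42 ± 0.38) and the chaperone Hspa5 (1.68 ± 0.36) rose, 2 of 18 in that list (2 adjusted over the list alone), with a Benjamini-Hochberg adjusted p = 0.0158, and adjusted p = 0.347 with an estimated correlation by limma's camera. The G1 cyclins Ccnd1 (-1.76 ± 0.24) and Ccnd2 (-0.86 ± 0.17) fell, as did the matrix and fibroblast markers Timp1 (-1.57 ± 0.23) and Thy1 (-3.17 ± 0.57), the gap junction gene Gja1 (-1.93 ± 0.42) and the sarcomere gene Ldb3 (-1.41 ± 0.26). These were 2 of 15 cell cycle inhibitors and G1 cyclins (1 higher and 4 lower adjusted over the list alone) and 2 of 17 fibroblast and matrix markers (6 adjusted over the list alone). Neither list passed limma's camera (Benjamini-Hochberg adjusted p = 0.198 and 0.0773). p53 targets had 1 of 27 genes higher, Ccng1 (1.23 ± 0.32), and 3 lower, Perp (-1.10 ± 0.26), Ei24 (-0.67 ± 0.17) and Pmaip1 (-1.03 ± 0.29) (2 and 5 adjusted over the list alone). Irf7 (-1.64 ± 0.32), Decr1 (-0.84 ± 0.20), Txn1 (-0.86 ± 0.21) and Ctsb (-0.69 ± 0.20) fell. The cell cycle gene Cdk1 (2.38 ± 0.67) and the iron and lipid genes Acsl4 (2.13 ± 0.32), Slc40a1 (1.41 ± 0.37) and Ireb2 (0.66 ± 0.16) rose. Of the reported miR-222 targets Hmbox1 (-1.97 ± 0.47, same controls) fell and Hipk1 (-0.47 ± 0.15) did not pass. Of the reported miR-455 targets Ei24 (-0.67 ± 0.17) and Runx2 (-1.27 ± 0.36) fell and Ubqln1 (0.87 ± 0.19) rose. Diablo (1.36 ± 0.19) and Ndufv2 (1.87 ± 0.30) rose.

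The combination with doxorubicin raised 397 genes and lowered 397. Pcsk1 was listed at 0 in the doxorubicin controls and was at least 163-fold higher with both mimics, at 10.8 ± 16.3 CPM (SD, n = 3), and at least 21.1-fold higher without doxorubicin combination replicate 2. Asb12 (4.36 ± 0.79), Kcnv2 (4.25 ± 0.60), Mstn (4.25 ± 0.87), Palmd (3.96 ± 0.87) and Med30 (3.74 ± 0.44) rose furthest beside it, and Dkk3 (-4.17 ± 0.29), Gca (-3.03 ± 0.41), Paqr6 (-3.03 ± 0.71), Ptn (-2.94 ± 0.65) and Ampd3 (-2.91 ± 0.49) fell furthest beside Thy1. Nppa (-1.43 ± 0.48), Nppb (-0.34 ± 0.36), Cdkn1a (-0.47 ± 0.57), Mdm2 (0.14 ± 0.44), Myh6 (0.63 ± 0.36), Myh7 (-1.75 ± 0.52) and Cdkn1b (0.00 ± 0.34) did not pass. The count was 463 without doxorubicin control replicate 2 and 509 without combination replicate 3. The 6 libraries fitted alone called 2 genes.

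**Figure D3:**
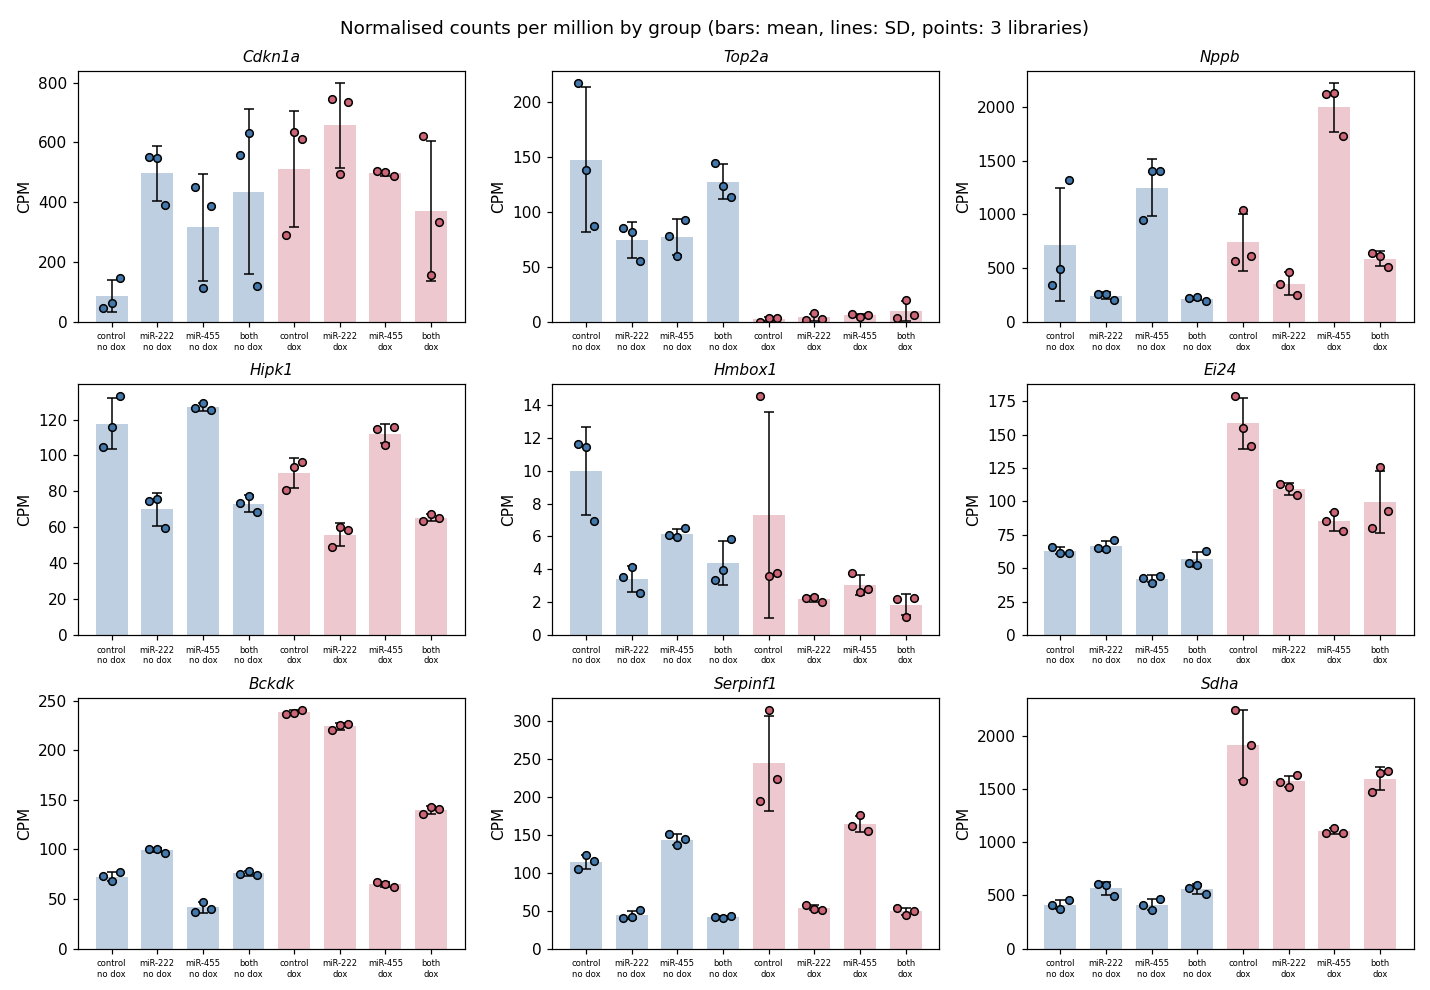
CPM of 9 named genes in each library of the 8 groups. Each point is 1 library, and the vertical axis is on a linear scale.

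Against miR-222 alone with doxorubicin, the combination lowered 23 genes and raised 0 by edgeR, with 1527 genes at an unadjusted p under 0.05 and 148 called by DESeq2. The pyruvate carrier gene Mpc2 (-3.04 ± 0.53), the potassium channel Kcnh2 (-2.58 ± 0.45), the actin regulator Arpc1a (-1.97 ± 0.25), Cmas (-1.84 ± 0.21), Coq2 (-1.98 ± 0.38) and Gltp (-1.92 ± 0.37) and the lipid enzyme Lpcat3 (-1.01 ± 0.20) were lower. Of the 23 genes, 19 had also fallen with miR-455 alone in doxorubicin, where 0.424 were expected if the calls were independent, and these 2 comparisons share no library. Over all 14303 genes the log2 fold changes of these comparisons correlated with Pearson r = -0.103. Without doxorubicin miR-455 on top of miR-222 changed 0 genes by edgeR, with 564 at an unadjusted p under 0.05 and no other tool run, and r with the miR-455 effect was -0.113. The mitochondrially encoded list was called higher (median 0.73, adjusted p = 0.0253, and adjusted p = 0.951 with an estimated correlation, limma's camera with Benjamini-Hochberg adjustment), with a median of -0.08 with 2 surrogate variables, chosen after the data were seen. In it edgeR and DESeq2 called 0 of 13, with 1 at an unadjusted p under 0.05. The share of these transcripts was 18.2% ± 4.46 (SD, n = 3) against 10.6% ± 2.04. The count was 8 with the replicate block and 0 in a fit of these 6 libraries alone. Nppa (-0.32 ± 0.47), Nppb (0.73 ± 0.37), Cdkn1a (-0.83 ± 0.58), Mdm2 (0.91 ± 0.44), Myh6 (0.55 ± 0.36) and Myh7 (0.28 ± 0.51) did not pass. Leaving out 1 library gave 11, 5 and 3 genes for miR-222 replicates 1 to 3 and 38, 6 and 5 for combination replicates 1 to 3, all with doxorubicin.

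Against miR-455 alone with doxorubicin, the combination lowered the natriuretic peptide genes Nppa (-2.04 ± 0.49) and Nppb (-1.77 ± 0.38). The reported miR-222 target Hipk1 (-0.78 ± 0.15), the cyclin Ccnd1 (-1.91 ± 0.24), the kinase Cdk6 (-1.83 ± 0.48), the interferon regulator Irf7 (-1.72 ± 0.32) and the sarcomere genes Ldb3 (-1.57 ± 0.26) and Myl2 (-0.99 ± 0.22) fell. Ccng1 (1.65 ± 0.33), Cdk1 (2.56 ± 0.67), Me1 (1.20 ± 0.19), Vldlr (2.03 ± 0.38), Slc40a1 (2.22 ± 0.38), Acsl4 (1.41 ± 0.31), Myom1 (2.03 ± 0.45) and Dcn (1.17 ± 0.25) rose. In all 222 genes rose and 133 fell, with Palmd (4.18 ± 0.88), Igfbp5 (3.18 ± 0.53), Slc1a1 (3.09 ± 0.81), Gucy1a1 (2.96 ± 0.65) and Alox15 (2.96 ± 0.71) and myostatin, Mstn (5.75 ± 0.94), furthest up and Krt7 (-3.42 ± 0.48), Ackr4 (-2.97 ± 0.36), Slc14a1 (-2.93 ± 0.55), Hmga2 (-2.85 ± 0.71), Mrpl36 (-2.76 ± 0.38) and Gna12 (-2.76 ± 0.34) furthest down. Of these, 77 lower and 59 higher genes had moved the same way with miR-222 alone in doxorubicin, where 3.14 and 3.52 were expected if the calls were independent. Over all genes Pearson r was 0.104. limma's camera called the immediate early genes lower (median -1.13, Benjamini-Hochberg adjusted p = 0.00926, and adjusted p = 0.935 with an estimated correlation), while edgeR called 0 of 20 (7 lower at an unadjusted p under 0.05, 2 adjusted over the list alone, and 2 by DESeq2). Cdkn1a (-0.43 ± 0.57), Mdm2 (0.53 ± 0.44), Myh6 (0.79 ± 0.36), Myh7 (-1.11 ± 0.51) and Cdkn1b (-0.74 ± 0.33) did not pass. Leaving out 1 library gave 118, 108 and 108 genes for miR-455 replicates 1 to 3 and 1039, 158 and 196 for combination replicates 1 to 3, all with doxorubicin.

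Whether the pair acts beyond the sum of its parts was tested as the combination effect minus both single effects on the log2 scale. Without doxorubicin the atrial light chain Myl4 (-2.96 ± 0.46) and the neuronal gene Cend1 (-3.18 ± 0.49) differed, each lower than the sum. Myl4 stood at 36.1 ± 8.78 CPM (SD, n = 3) with the control mimic, 88.0 ± 4.00 with miR-222, 325 ± 24.4 with miR-455 and 102 ± 4.74 with both. With doxorubicin 5 genes were higher than the sum, Gca (3.27 ± 0.56), Sqor (2.29 ± 0.41), Vnn1 (2.15 ± 0.33), Tmem183a (1.48 ± 0.25) and Bckdk (1.20 ± 0.19), and Cmas (-1.89 ± 0.30) was lower. Gca, a calcium-binding protein gene, was at 36.5 CPM with the control mimic and 3.68, 4.58 and 4.47 CPM with miR-222, miR-455 and both, so the combination stayed near each single mimic. Cell cycle genes without doxorubicin were higher than the sum (median 1.35) with a Benjamini-Hochberg adjusted p = 8.45e-15, and adjusted p = 0.0215 with an estimated correlation by limma's camera. Single-gene tests by edgeR called 0 of 30 (14 higher at an unadjusted p under 0.05, 13 adjusted over the list alone, and 6 by DESeq2). Beside this the mitochondrially encoded list was higher than the sum (median 2.44) with a Benjamini-Hochberg adjusted p = 5.01e-05, and adjusted p = 0.669 with an estimated correlation by limma's camera, and these transcripts took 24.9% of combination replicate 3. Without this and the 3 other libraries with the fewest genes the cell cycle median was 1.19. The median over all genes in this test was -0.12, and -0.11 with DESeq2 size factors. The counts of 2 and 6 genes by edgeR compare with 2636 and 1644 at an unadjusted p under 0.05 and 249 and 189 by DESeq2. With doxorubicin no filter and a fit of these 12 libraries alone gave 0 each, and the replicate block 1. In simulated data with 50 genes changed 4-fold beyond the sum with doxorubicin, 16 were called. Without doxorubicin the count was 7 without control replicate 3, 1 without miR-455 replicate 2, and 0 without control replicate 1 or 2, miR-222 replicate 2 or 3, miR-455 replicate 1 or 3, or any 1 combination library. With doxorubicin it was 10 and 14 without control replicate 2 and 3, 2 without miR-222 replicate 1, 24 without combination replicate 1, and 0 without miR-222 replicate 2 or 3, any 1 miR-455 library, or combination replicate 2 or 3.

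Whether a mimic changed the response to doxorubicin was tested as the difference between the doxorubicin effect with the mimic and that with the control mimic. The p53 target list responded less with miR-222 (median difference -0.93) and with both mimics (-1.14). limma's camera gave Benjamini-Hochberg adjusted p = 4.36e-07 and 2.95e-05, and 0.0108 and 0.047 with an estimated correlation. Both calls held and share their controls. edgeR called 0 of the 27 genes in each case, with 9 and 10 lower at an unadjusted p under 0.05, 2 and 4 adjusted over the list alone, and 2 and 3 by DESeq2. With 6 libraries against 6, p53 targets were higher with miR-222 without doxorubicin (median 0.58) and not with it (-0.15). For miR-222 the difference lay mainly without doxorubicin. The autophagy and lysosome list also responded less with miR-222 (median difference -0.70), with a Benjamini-Hochberg adjusted p = 1.61e-04, and adjusted p = 0.0108 with an estimated correlation by limma's camera. By edgeR 0 of 19 were called (7 lower at an unadjusted p under 0.05, and 1 by DESeq2). For the interferon-stimulated genes the median difference was -2.00 with miR-222 and -1.67 with both mimics, with Benjamini-Hochberg adjusted p = 9.95e-07, and adjusted p = 0.118 with an estimated correlation and adjusted p = 0.00127, and adjusted p = 0.413 with an estimated correlation by limma's camera. By edgeR 0 of 21 were called (12 and 9 lower at an unadjusted p under 0.05, 9 and 7 adjusted over the list alone, and 4 and 6 by DESeq2).

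In this test of the response with miR-222 edgeR called 1 gene higher, Fam13a (3.34 ± 0.59), and 6 lower, among them Ephx1 (-2.38 ± 0.39), Fgf1 (-2.48 ± 0.44) and Plcd4 (-2.40 ± 0.41) and the heme lyase gene Hccs (-1.64 ± 0.30). With both mimics it called 1 gene higher, Nedd9 (1.79 ± 0.33), and 7 lower, among them Hccs (-1.75 ± 0.30), Nap1l4 (-1.45 ± 0.25) and Arl2bp (-1.19 ± 0.21) and the adrenergic receptor Adra1d (-4.63 ± 0.78). With miR-455 edgeR called 0 genes, with 1523 at an unadjusted p under 0.05, 135 called by DESeq2 and 6141 by limma-voom with quality weights, a setting chosen after the data were seen. Unadjusted p under 0.05 was reached by 1404 genes for miR-222 and 2002 for both, and DESeq2 called 205 and 371. The calls for miR-222 ended (0 genes) with DESeq2 size factors, a filter of 1 CPM in 3 libraries or a block for the replicate number, and those for both with no filter, the block or a fit of these 12 libraries alone, which left 1 for miR-222. In simulated data with 50 genes changed 4-fold in the interaction of the combination, 11 were called. For miR-222 the count was 13 without miR-222 replicate 3, 1 without doxorubicin control replicate 3 or doxorubicin miR-222 replicate 2, and 0 without control replicate 1 or 2, miR-222 replicate 1 or 2, doxorubicin control replicate 2 or doxorubicin miR-222 replicate 1 or 3. For miR-455 it was 56 without miR-455 replicate 2, 7 and 2 without doxorubicin control replicates 2 and 1, and 1 without control replicate 1 or doxorubicin control replicate 3. For both mimics it was 894 without combination replicate 3, 16, 2 and 1 without doxorubicin control replicates 1 to 3, 31 and 0 without doxorubicin combination replicates 1 and 3, and 0 without control replicate 1 or 2 or combination replicate 1 or 2.

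**Figure D4:**
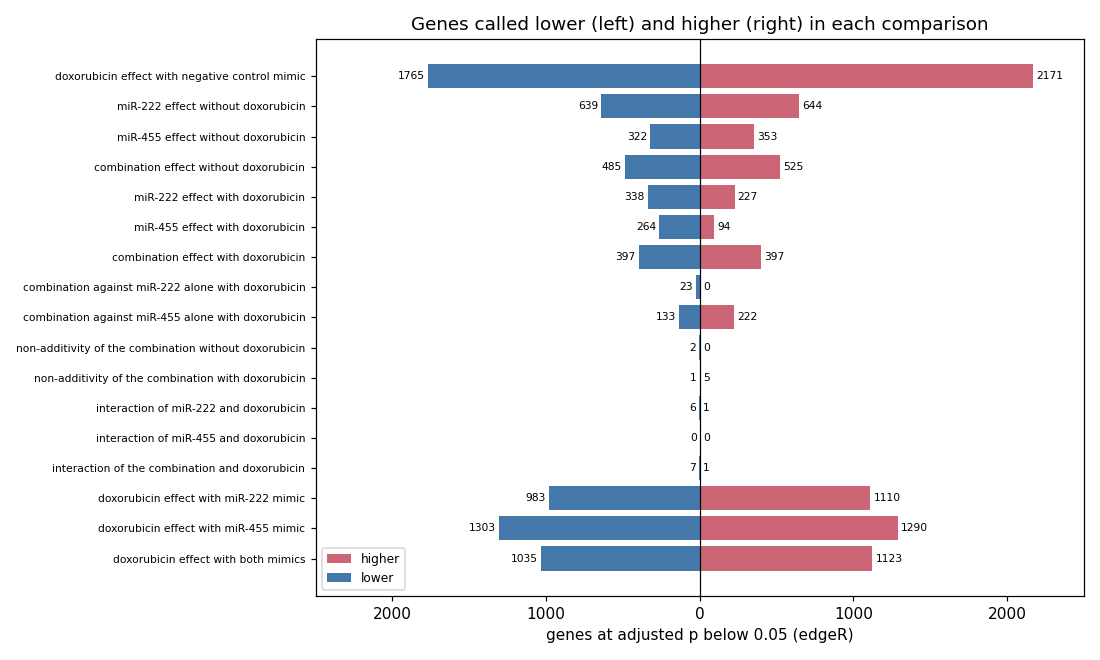
Number of genes called higher and lower by edgeR at a Benjamini-Hochberg adjusted p under 0.05 in each comparison.

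The direction of each mimic effect with doxorubicin was set against the doxorubicin response of the 2 mimic arms that share no library with it, for genes that responded by at least 2-fold. For miR-222, 63.6% of 2713 such genes moved opposite to the response (median along it -0.26). It was 65.5% of 2636 for the combination (-0.29) and 54.5% of 2512 for miR-455 (-0.06). Genes that doxorubicin raised had median effects of -0.38 (miR-222) and -0.47 (combination), and lowered genes 0.12 and 0.08. Fry in limma put miR-222 and the combination under 0.05 before adjustment over the 3 mimics and neither after it. The Benjamini-Hochberg adjusted p = 0.0722 for miR-222, 0.063 for the combination and 0.357 for miR-455, an adjustment added after the values were seen. Over the alternatives these adjusted p ran from 1.09e-04 to 0.293 for miR-222 and from 9.88e-04 to 0.293 for the combination (limma, Benjamini-Hochberg). The unadjusted value stayed under 0.05 in 8 of 18 fits that left out 1 library for miR-222 and in 15 of 18 for the combination. It was highest without miR-455 replicate 2 for miR-222 (0.168) and without doxorubicin combination replicate 2 for the combination (0.132). Without the 4 libraries with the fewest genes the medians were -0.18 and -0.12, and lowered genes of the combination moved along the response (-0.20).

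Mimic effects were set side by side without and with doxorubicin, in comparisons that share no library. Across 14303 genes, which are not independent replicates, the log2 fold changes correlated with Pearson r = 0.404 for miR-222, 0.283 for miR-455 and 0.18 for both. For miR-222, 168 genes were lower in both states and 91 higher, where 15.1 and 10.2 were expected if the calls were independent. Hipk1 was among the lower ones. For miR-455 the shared genes numbered 68 lower and 42 higher (5.94 and 2.32 expected), and for both mimics 148 and 99 (13.5 and 14.6 expected).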

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

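Each result here stands out because a test of the difference between groups passed. The test of glycolysis genes with doxorubicin, the pattern of genes changed alike and the test without the 4 libraries with the fewest genes were chosen after the result was seen. Groups of 3 libraries were not tested for a library far from the others. After each gene stands its log2 difference (edgeR, Benjamini-Hochberg adjusted p under 0.05), and after each list its median log2 difference, the adjusted p of limma's camera and the adjusted p with an estimated correlation (Benjamini-Hochberg).

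The combination minus the sum of both single effects without doxorubicin differed from 0 for Myl4 (-2.96) and Cend1 (-3.18), and for the lists sarcomere (-0.57, 0.00749, 0.669), nuclear oxidative phosphorylation (-0.61, 0.00749, 0.669), mitochondrially encoded (2.44, 5.01e-05, 0.669), fatty acid oxidation (-0.74, 0.00749, 0.669), glycolysis (-1.33, 7.44e-05, 0.669), cell cycle (1.35, 8.45e-15, 0.0215) and DNA repair (1.04, 0.00184, 0.669). With doxorubicin the genes were Gca (3.27), Sqor (2.29), Vnn1 (2.15), Tmem183a (1.48), Bckdk (1.20) and Cmas (-1.89), and the lists calcium handling and ion channels (0.73, 0.0121, 0.509) and mitochondrially encoded (1.53, 0.00505, 0.878). Of 100 splits of the libraries, the real one included, 9 called at least the 2 genes found without doxorubicin, with up to 1822 in another split, and 6 at least the 6 found with it, with up to 202, so chance cannot be excluded for these counts. Splits that call several times the real count point to a structure of the libraries that the labels do not name.

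The doxorubicin response with miR-222 minus that with the control mimic differed for Fam13a (3.34), Hccs (-1.64), Ephx1 (-2.38), Plcd4 (-2.40), Fgf1 (-2.48), Sel1l3 (-8.42) and Slc4a1 (-9.61). The values of Sel1l3 and Slc4a1 depend on the prior count, since both genes are listed at 0 with the control mimic alone. The lists were p53 targets (-0.93, 4.36e-07, 0.0108), sarcomere (-0.46, 0.0035, 0.413), calcium handling and ion channels (-0.45, 0.0089, 0.327), cardiac stress genes (1.21, 0.018, 0.414), nuclear oxidative phosphorylation (-0.79, 3.21e-08, 0.228), fatty acid oxidation (-0.94, 8.52e-09, 0.228), glycolysis (-0.85, 0.0035, 0.637), NRF2 antioxidant response (-0.29, 0.00976, 0.346), autophagy and lysosome (-0.70, 1.61e-04, 0.0108), interferon-stimulated genes (-2.00, 9.95e-07, 0.118), cell cycle (0.63, 1.46e-04, 0.228), fibroblast and matrix (0.17, 0.0274, 0.389) and smooth muscle and pericyte (0.90, 0.0261, 0.282). Of 100 splits 14 called at least the 7 genes found, with up to 366 in another split, so chance cannot be excluded. For miR-455 no gene passed edgeR, with 1523 at an unadjusted p under 0.05 and 135 by DESeq2, and the lists were p53 targets (-0.52, 0.0036, 0.195), sarcomere (-0.78, 1.77e-06, 0.309), calcium handling and ion channels (-0.71, 0.00287, 0.316), nuclear oxidative phosphorylation (-0.78, 1.11e-06, 0.316), mitochondrially encoded (0.64, 0.00287, 0.622), fatty acid oxidation (-0.82, 1.97e-05, 0.429), glycolysis (-1.03, 7.14e-06, 0.486), autophagy and lysosome (-0.56, 0.0221, 0.195), cell cycle (0.79, 6.34e-06, 0.195) and DNA repair (0.75, 0.0221, 0.486). The real count is 0, which all 100 splits reach (up to 265 genes), so the splits decide nothing here.

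For both mimics the response differed for Nedd9 (1.79), Arl2bp (-1.19), RGD1310352 (-1.25), LOC306766 (-1.42), Nap1l4 (-1.45), Hccs (-1.75), Adra1d (-4.63) and Slc4a1 (-9.51), and the lists were p53 targets (-1.14, 2.95e-05, 0.047), cardiac stress genes (1.34, 0.0274, 0.731), nuclear oxidative phosphorylation (-0.90, 1.13e-06, 0.413), fatty acid oxidation (-1.05, 8.84e-07, 0.413), glycolysis (-0.95, 0.0101, 0.778), NRF2 antioxidant response (-0.46, 0.00858, 0.452), autophagy and lysosome (-0.50, 0.0101, 0.115), interferon-stimulated genes (-1.67, 0.00127, 0.413) and cell cycle (0.65, 0.0101, 0.58). Of 100 splits 27 called at least the 8 genes found, with up to 6386 in another split, so chance cannot be excluded and the split with 6386 points to a structure of the libraries. The fitted value of Slc4a1 again depends on the prior count.

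limma's camera called the glycolysis list higher with each mimic without doxorubicin, with medians of 1.35, 1.37 and 1.35 and a mean of 1.36. Only 3, 1 and 1 of its 23 genes passed edgeR, and with an estimated correlation camera lost the calls (Benjamini-Hochberg adjusted p = 0.459, 0.457 and 0.403). A hypoxia-gene state of single libraries may explain part of these medians. With the mean of 15 hypoxia genes outside the list as a covariate the mean of the 3 medians was 0.365. This was below the 0.5 set beforehand by less than 0.307, the median SE of the single genes of the list. The error of the mean of the medians was not computed, so the bounds are judged by this single-gene SE alone. Since mimics can themselves cause such a state, the covariate could also remove an effect of theirs. The share of mitochondrial transcripts as a covariate left 1.03 (SE 0.439), and with doxorubicin, in other libraries, the mean was 0.377 (SE 0.477). The first stays over 0.5 by more than that SE, which spans the bound of 1 set against that share, and the second spans 0.5. These explanations cannot be told apart.

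Some genes changed alike with all 3 mimic treatments: 155 higher and 85 lower without doxorubicin, 53 and 63 with it. In both states 20 were higher and 13 lower, where 0.574 and 0.374 were expected if the calls were independent, among them Med30, Galc, Diablo and Agpat5 higher and Col4a4, Vnn1, Ptn and Itgb1 lower. The control libraries differ between the states, so a chance deviation of the controls of 1 state alone would not give these 33. For shared control libraries, 20 further simulations of unchanged groups gave 0 genes alike by edgeR. They called at most 1 gene in any comparison, so the bound set beforehand, that no simulation gives as many, had to be met and decides nothing. A property of the control mimic stays open as well. For 239 genes chosen without doxorubicin, the combination effect with doxorubicin divided by the sum of both single effects had a median of 0.548 (jackknife SE over libraries 0.0479), where 0.5 is one step shared by every mimic and 1 is adding up. The same genes in the simulated unchanged groups had 0.325 (0.27 to 0.407), also under the bound of 0.75, since the effects share their controls. A mix of unchanged genes and effects that add up could give 0.548 too, and so could a saturating response, so these cannot be told apart.

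The miR-222 and combination effects ran opposite to the doxorubicin response, with medians of -0.264 and -0.286 along it, and neither passed after adjustment over the 3 mimics. A lessened response is the biological explanation the design names, and it stays open. Without the 4 libraries with the fewest genes the higher of both medians was -0.124 (jackknife SE 0.0835 and 0.0507), between the bounds set, so those libraries may carry part of it. With the mitochondrial share as a covariate it was -0.283 (SE 0.260 and 0.256), an error too wide to decide, so these causes cannot be told apart.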

How the results depend on the processing

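Leaving out the 4 libraries with the fewest genes, 2 and 4 surrogate variables and library quality weights were chosen after the data were seen. Gene values were compared under DESeq2 size factors, the DESeq2 test, the replicate block, each library left out, the 4 libraries left out, and 2 or 4 surrogate variables. The genes named in the text did not reverse in these. Lists were compared under the block, the 4 libraries left out, surrogate variables, fry and an estimated correlation, and 1 reversed. The other settings gave counts alone. Of 394 gene values, 381 stayed on their side of the threshold with DESeq2 size factors, 386 with the DESeq2 test, and 338 with a block for the replicate number. It was 376 without the 4 libraries, 370 with 2 and 377 with 4 surrogate variables, and 1759 of 2472 with 1 library left out. The mitochondrially encoded list for both mimics over miR-222 with doxorubicin had a median of -0.0784 with 2 surrogate variables, in place of 0.73, and the cause was not tested. Of 90 list calls over 392 tests, which leave out doxorubicin with a mimic, 89 were shared with the replicate block, 70 without the 4 libraries, 65 with 2 and 74 with 4 surrogate variables. It was 41 with fry, which called 67, and 47 with its mixed form, which called 126. With an estimated correlation camera called 7. For doxorubicin with a mimic 8 of 30 calls in 84 tests held with it. Replicate numbers do not pair the libraries. The 84 pairs with the same number had a mean correlation of -0.0277 after group means were removed, against 0.0190 in 168 other pairs, so the block is a check alone. Depth limits genes with few counts, since a group at 0 can hide up to 3 counts. In simulated data 9 of 50 genes changed 2-fold by doxorubicin were called, and 0 of 50 for the combination beyond the sum with doxorubicin. The planned tests of seed sites, of 8mer sites alone and of GC content were not run.

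Counts of called genes that moved by more than 1.5 times are given by setting; the cause was not tested unless stated. Without the 4 libraries with the fewest genes, edgeR called 2832 (miR-222), 1994 (miR-455), 3714 (both), 1211 (miR-222 in doxorubicin), 727 (miR-455 in doxorubicin), 1873 (both in doxorubicin), 91 (both over miR-222) and 779 (both over miR-455). The same setting gave 4 (beyond the sum), 35 (beyond the sum in doxorubicin), 148 (interaction of miR-222), 63 (interaction of miR-455), 1589 (interaction of both), 4906 (doxorubicin in miR-222), 5545 (doxorubicin in miR-455) and 4757 (doxorubicin in both). With 2 surrogate variables it called 6555 (doxorubicin), 2034 (miR-222), 2425 (both), 2125 (miR-222 in doxorubicin), 1416 (miR-455 in doxorubicin), 3016 (both in doxorubicin), 99 (both over miR-222) and 927 (both over miR-455). The same setting gave 30 (beyond the sum), 97 (beyond the sum in doxorubicin), 516 (interaction of miR-222), 127 (interaction of miR-455), 1008 (interaction of both), 4966 (doxorubicin in miR-222), 4793 (doxorubicin in miR-455) and 5448 (doxorubicin in both). With 4 of them it called 6522 (doxorubicin), 2766 (miR-222), 1587 (miR-455), 3680 (both), 2355 (miR-222 in doxorubicin), 1651 (miR-455 in doxorubicin), 2459 (both in doxorubicin), 124 (both over miR-222) and 1046 (both over miR-455). The same setting gave 49 (beyond the sum), 125 (beyond the sum in doxorubicin), 448 (interaction of miR-222), 167 (interaction of miR-455), 669 (interaction of both), 5755 (doxorubicin in miR-222), 5415 (doxorubicin in miR-455) and 6111 (doxorubicin in both). limma-voom with quality weights called 7449 (doxorubicin), 9090 (miR-222), 8755 (miR-455), 9150 (both), 2214 (miR-222 in doxorubicin), 1742 (miR-455 in doxorubicin), 3444 (both in doxorubicin), 2238 (both over miR-222) and 3791 (both over miR-455). The same setting gave 7390 (beyond the sum), 651 (beyond the sum in doxorubicin), 4882 (interaction of miR-222), 6141 (interaction of miR-455), 6782 (interaction of both), 8518 (doxorubicin in miR-222), 9574 (doxorubicin in miR-455) and 7114 (doxorubicin in both). The DESeq2 test called 2376 (miR-222), 1918 (miR-455), 1887 (both), 1047 (miR-222 in doxorubicin), 654 (miR-455 in doxorubicin), 1532 (both in doxorubicin) and 148 (both over miR-222). The same setting gave 1002 (both over miR-455), 249 (beyond the sum), 189 (beyond the sum in doxorubicin), 205 (interaction of miR-222), 135 (interaction of miR-455) and 371 (interaction of both). Fits of only the libraries compared called 1437 (doxorubicin), 485 (miR-222), 2 (miR-455), 0 (both), 76 (miR-222 in doxorubicin), 144 (miR-455 in doxorubicin), 2 (both in doxorubicin) and 0 (both over miR-222). The same setting gave 94 (both over miR-455), 0 (beyond the sum in doxorubicin), 1 (interaction of miR-222), 0 (interaction of both), 4785 (doxorubicin in miR-222), 5419 (doxorubicin in miR-455) and 5 (doxorubicin in both). The replicate block gave 377 (miR-455), 8 (both over miR-222), 1 (beyond the sum in doxorubicin), 0 (interaction of miR-222) and 0 (interaction of both). A filter of 1 CPM in 3 libraries gave 13 (beyond the sum in doxorubicin), 0 (interaction of miR-222) and 13 (interaction of both). No filter gave 15 (both over miR-222), 0 (beyond the sum in doxorubicin) and 0 (interaction of both). DESeq2 size factors gave 0 (interaction of miR-222). Covariate fits were counted for the mimic effects alone. The hypoxia-gene covariate gave 743 (miR-222), 161 (miR-455), 612 (both), 995 (miR-222 in doxorubicin), 574 (miR-455 in doxorubicin) and 1399 (both in doxorubicin), and the mitochondrial covariate 317 (miR-455), 1853 (both), 1004 (miR-222 in doxorubicin), 673 (miR-455 in doxorubicin) and 1901 (both in doxorubicin).

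Leaving out each library gave counts from 2892 to 4297 (doxorubicin), 300 to 1644 (miR-222), 16 to 1987 (miR-455), 267 to 2718 (both), 263 to 532 (miR-222 in doxorubicin) and 145 to 320 (miR-455 in doxorubicin). They ran from 463 to 1180 (both in doxorubicin), 3 to 38 (both over miR-222), 108 to 1039 (both over miR-455), 0 to 7 (beyond the sum), 0 to 24 (beyond the sum in doxorubicin) and 0 to 13 (interaction of miR-222), and from 0 to 56 (interaction of miR-455), 0 to 894 (interaction of both), 1187 to 1742 (doxorubicin in miR-222), 1542 to 2584 (doxorubicin in miR-455) and 1330 to 2914 (doxorubicin in both). The median along the doxorubicin response ran from -0.323 to -0.196 (miR-222), -0.116 to -0.00969 (miR-455) and -0.38 to -0.133 (both). It was -0.181 for miR-222 and -0.124 for both without the 4 libraries, and -0.154 for miR-222 with no minimum fold, none at a p under 0.05, and -0.0707 for miR-455 with 2 surrogate variables, at a p under 0.05.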

Other observations

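Pooling the libraries by mimic averages its effect over the presence of the other mimic, a contrast chosen after the data were seen. Values are log2 fold changes ± SE without and with doxorubicin, from 6 libraries with the mimic against 6 without it. With miR-222, Serpinf1 (-1.58 ± 0.12, -1.97 ± 0.13) and Col4a4 (-2.12 ± 0.14, -1.55 ± 0.13) fell in both states. Igfbp5 (3.84 ± 0.39, 2.98 ± 0.37) rose in both. Of 559 and 556 genes lower by edgeR (Benjamini-Hochberg adjusted p under 0.05) 242 were shared, and of 554 and 561 higher 175, where 21.7 each were expected if the calls were independent.

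With miR-455, Nt5e (-1.47 ± 0.17, -1.39 ± 0.17) and Glb1 (-1.01 ± 0.15, -1.52 ± 0.15) fell in both states. Erlin2 (0.65 ± 0.13, 1.02 ± 0.13) rose in both. The shared genes numbered 53 of 85 and 221 lower, and 22 of 75 and 96 higher, where 1.31 and 0.503 were expected.

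The 6 libraries of a comparison can be split in 10 ways, the real one included, too few for a share under 0.05. The real count and the highest other were 3936 and 1717 for doxorubicin with the control mimic, 2093 and 0 with miR-222, 2593 and 0 with miR-455, and 2158 and 2455 with both. Without doxorubicin they were 1283 and 0 for miR-222, 675 and 75 for miR-455, and 1010 and 3987 for both mimics. With doxorubicin they were 565 and 0, 358 and 0, and 794 and 2357, and for both mimics over miR-222 and over miR-455 they were 23 and 0, and 355 and 0. Each highest other of 0 is a count of genes by edgeR, and other tools were not run on these splits. In the 3 comparisons of both mimics with a higher count elsewhere, 2 splits reached the real count, and in the other comparisons 1, the real one. The splits with 3987 and 2357 genes call several times the real count and point to a structure of the libraries. They set control replicates 1 and 2 with combination replicate 3 apart from the rest, and likewise doxorubicin control replicate 1 with doxorubicin combination replicates 2 and 3. The split with 2455 set combination replicates 1 and 2 with doxorubicin combination replicate 1.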
